A study of Mus musculus with 2 samples.

How the data were processed

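Small RNA was sequenced from forebrain tissue of mouse embryos at 10.5 days of development, of strain B6NCrl and mixed sex. The samples form 1 group of 2 libraries. Replicate 1 was made from tissue pooled from 69 embryos and replicate 2 from tissue pooled from 51 embryos, and the labels number them as biological replicates from separate biosamples. Per the labels, the libraries held fragments shorter than 30 nt and the assembly was mm10.

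The deposited files hold raw counts of reads per gene, with no normalization. They carry 1973 gene identifiers and 4 tallies of reads that belong to no gene. Per the authors' file notes, the gene set was genome annotation M4. The aligner, its version, the adapter trimming and the counting program are not given in the sources used here. Each file has a count of reads on either strand, a count on the strand of the gene and a count on the opposite strand. The count on the strand of the gene was used throughout, because it held 96.5% ± 0.22 (SD, n = 2) of the counts on either strand. On its own, the opposite-strand count appears only beside the Dlk1-Dio3 share, on the map of that region and in the closing section. The tallies, left out of library sizes and tests, held 25.0% ± 0.61 of the reads as unmapped, 29.4% ± 0.95 as mapped to several places and 6.70% ± 1.02 as mapped outside the listed genes (SD, n = 2). No read was tallied as ambiguous.

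Reads that mapped to several places were given to no gene by the deposited counts. A miRNA whose mature sequence is made from several loci, such as miR-9, miR-124 or let-7a, was therefore counted only through reads that mapped to 1 locus, and its level is a lower limit. The 120 genes of this kind, recognised by symbols that differ only in a trailing locus number, together held 2.65% of the counts.

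Gene symbols, coordinates and gene context came from GENCODE release M21, which uses the same mm10 build. Of the 1973 identifiers, 1894 were found in it, 1815 of them with the same version. The 79 others held 8 counts in the 2 libraries together and stayed in the totals without a symbol. Counts were scaled to CPM on the total of the gene counts. Ratios between the libraries used the TMM factors of edgeR 4.0.16 (R 4.3.3) and a pseudocount of 0.5 counts, and are replicate 1 over replicate 2 on the log2 scale. Levels on the log2 scale used a pseudocount of 1 CPM. Genes with a mean count of 10 or more, 401 in number, entered the ratios and tests. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

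The spread between replicates was summarised as the biological coefficient of variation from the common dispersion of edgeR. An exact binomial test, two-sided, asked for each gene whether its counts split between the libraries as their sizes do, with Benjamini-Hochberg adjustment over 401 genes and a threshold of 0.05. It covers counting error only and compares these 2 libraries. With 1 group there was no comparison between conditions. A gene counts as rising or falling below only where it passed that test.

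Before the data were examined, 21 lists of miRNA genes were written down, grouped by the tissue, cell type, family or genomic cluster they are known from, together with 7 ratios between lists. They name 252 symbols, of which 227 were matched. Shares of single libraries carry exact Clopper-Pearson intervals at 95%, which cover counting error only, since reads copied by PCR are not independent molecules. The median of a list was placed among 10000 random lists of the same size. For ratios, the random genes were matched on mean level in 8 bins, and a list is said to stand apart when its percentile is under 2.5 or over 97.5. Random genes were drawn 1 by 1, so percentiles can be too extreme for lists whose genes vary together, such as genomic clusters. Genes on the same strand within 10 kb of each other formed a cluster, and a permutation test with 100000 shuffles of genes over clusters asked whether genes of a cluster were alike. A count of 0 allows up to 3 counts, which is 0.921 CPM in replicate 1 and 0.839 CPM in replicate 2.

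The named genes follow a rule set in advance. They are the 15 miRNA genes with the highest mean CPM, the 2 highest members of each list, and the 5 highest and 5 lowest log2 ratios among genes with a mean count of 100 or more. Genes named outside the rule are marked as chosen after their values were seen. Members with several loci are named as uncertain.

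The procedures were tested on simulated data. For 401 genes drawn at the real depths, the binomial test called 63% of genes made 1.25-fold different, 82% of genes made 2-fold different and 3.48% of unchanged genes. For 414 clustered genes, the permutation test found a cluster effect in 100% of simulated sets that had one and in 4.5% of those that had none. Lists of 10 genes shifted by 0.50 on the log2 scale stood apart in 77% of simulated lists and unshifted lists in 5.5%. The simulated genes of these lists varied independently, so the rates do not cover lists of genes that vary together.

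The alternatives tried were total-count scaling, size factors of DESeq2 1.42.0, other filters, other pseudocounts, other cluster distances, counts on either strand, totals without the most abundant gene, genes of several loci left out, and each replicate left out. Their effect is given in the closing section. For the check of base composition, hairpin GC content was taken from the M21 transcripts.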

Results

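Small RNA was counted per miRNA gene in the mouse embryonic forebrain at 10.5 days of development, when the cerebral vesicles are made mostly of dividing neuroepithelial cells. The 2 libraries came from pools of 69 embryos (replicate 1) and 51 embryos (replicate 2). Replicate 1 gave 8559330 reads, of which 3256070 were counted on the strand of a gene, and replicate 2 gave 9664755 reads, of which 3574530 were counted. Reads that mapped to several places, 2577249 in replicate 1 and 2780180 in replicate 2, were given to no gene. Coordinates are 1-based positions in mm10.

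The counted forebrain miRNA reads were dominated by a small number of genes. Reads that mapped to several places came to 79.2% of the gene counts in replicate 1 and 77.8% in replicate 2. Ranks and shares therefore hold for the counted reads only, and a miRNA of several loci could rank higher. Mir335, which lies in an intron of the imprinted gene Mest, was the most abundant, with 154722 ± 3859 CPM (SD, n = 2). Mir17 and Mir20a of the miR-17-92 cluster followed with 96278 ± 3351 and 36348 ± 1159 CPM, and then Mir130a with 31916 ± 1106 CPM and Mir126a, a miRNA of endothelial cells, with 30480 ± 2051 CPM. Mir99a reached 29039 ± 3050 CPM. The single gene Mir335 thus held 15.5% ± 0.39 of the counts, the 10 highest genes held 47.1% ± 0.42 and the 100 highest held 94.5% ± 0.0093 (SD, n = 2). At least 10 counts were found for 405 genes in replicate 1, 406 in replicate 2 and 385 in both, while 1234 of the 1973 genes had no count in either library.

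Mir335 (ENSMUSG00000065501.1) is on chromosome 6, positions 30741299 to 30741396 on the plus strand. Mir17 (ENSMUSG00000065508.1) occupies positions 115043671 to 115043754 of chromosome 14, in an exon of the long non-coding host gene Mir17hg, and Mir20a and Mir18 lie in the same host. Mir130a is intergenic on chromosome 2, at 84741115 to 84741178. Mir126a, at 26591357 to 26591429 of chromosome 2, overlaps an exon of Egfl7, a gene of endothelial cells. The remaining genes of the top 15 were Mir30e in an intron of Nfyc (23936 ± 50 CPM), Mir26b in an intron of Ctdsp1 (23044 ± 1028 CPM), Mir99b in an intron of Spaca6 (22564 ± 1380 CPM), Mir93 and Mir106b within Mcm7 (22373 ± 266 and 14390 ± 368 CPM), Mir92b (18228 ± 1668 CPM), Mir487b (15551 ± 1881 CPM), Mir322 (14692 ± 535 CPM) and Mir18 (14676 ± 567 CPM).

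Proliferation-linked, progenitor and imprinted miRNAs made up most of the counts that fell into the lists, which together held 61.8% ± 1.08 of all counts. The miR-17-92 cluster and its paralogs, known from dividing cells, held 22.6% ± 0.68 of the counts. The neural progenitor list held 12.2% ± 0.97, led by Mir130a, Mir99a, Mir99b and Mir92b. Its members were fixed in advance, and which cells these counts came from was not tested. The Dlk1-Dio3 cluster, which is expressed from the maternal chromosome, held 11.6% ± 1.28, led by Mir487b and Mir431 (13330 ± 1630 CPM). Its 44 counted genes span chromosome 12 from 109563692, where Mir770 starts, to Mir410, which starts at 109743715. Mir409, Mir376a, Mir380 and Mir299a of this region were not among the counted genes, so the share leaves them out and the leaders hold for counted genes only. Opposite-strand reads at the position of Mir409 numbered 52892 in replicate 1 and 68806 in replicate 2. Mir487b had 46303 and 60341 counts. If those reads stem from Mir409, it would lead the cluster and enter the top 15.

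**Figure D1:**
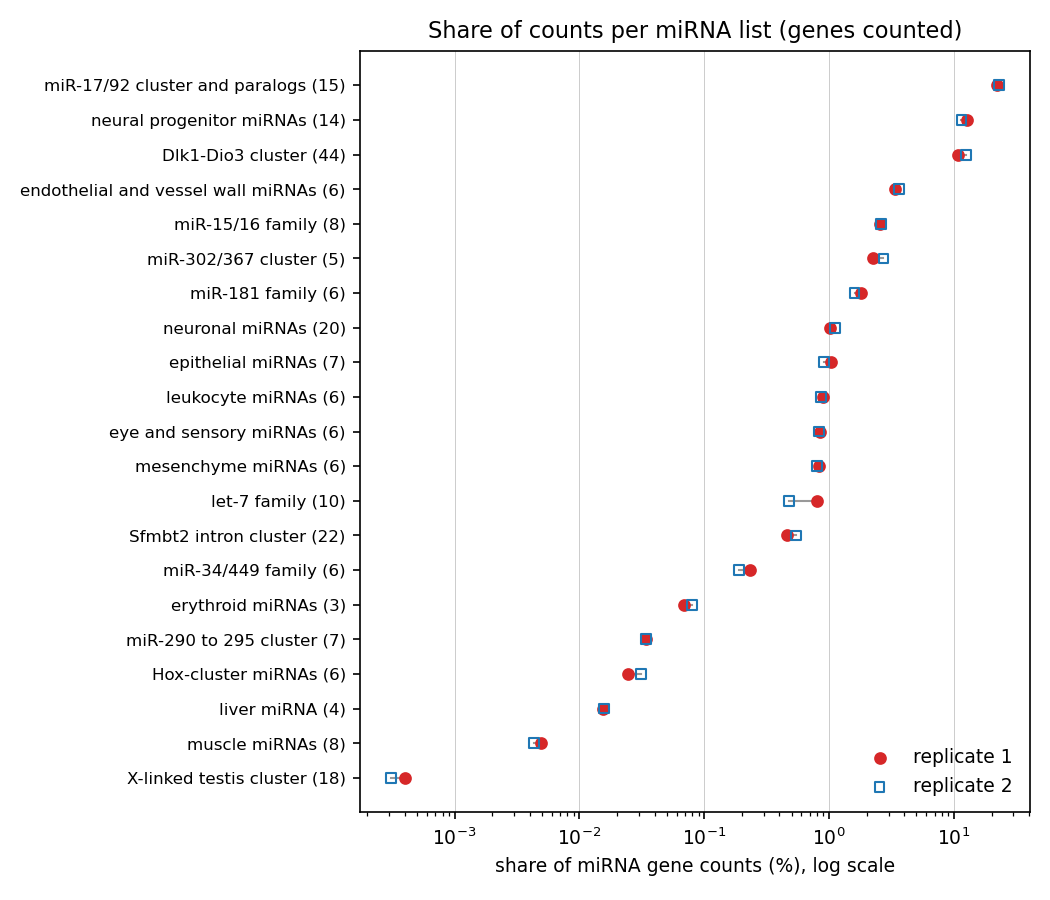
Share of the miRNA gene counts in each list, in percent on a log scale, with the number of counted genes per list in brackets. Filled circles stand for replicate 1 and open squares for replicate 2. The shares run from 22.6% for the miR-17-92 cluster and paralogs to 0.00035% for the X-linked testis cluster, and the widest gap among lists above 0.1% is that of the let-7 family, at 0.795% and 0.477%.

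Early embryo miRNAs were still present in the forebrain at this stage. The miR-302 cluster, known from pluripotent cells and the early embryo, held 2.48% ± 0.35 of the counts, with Mir302a at 9828 ± 1581 CPM and Mir302d at 7853 ± 971 CPM, both on the opposite strand of an intron of Larp7 on chromosome 3. The miR-290 cluster of embryonic stem cells held 0.0341% ± 0.00022, led by Mir293 (176 ± 2.7 CPM) and Mir292 (64.0 ± 2.4 CPM). The let-7 family, which accumulates as cells differentiate, held 0.636% ± 0.225, led by Mirlet7g (4038 ± 1331 CPM) and Mirlet7i (1640 ± 681 CPM), without Mirlet7e, which was not among the counted genes. The miR-17-92 list exceeded the let-7 list by 5.20 ± 0.56 on the log2 scale and the miR-302 list lay at −3.20 ± 0.16 against the miR-17-92 list (SD, n = 2). Of the 10 counted let-7 genes 5 are genes of several loci, against 4 of 15 in the miR-17-92 list. The let-7 share is therefore a lower limit, and its gap to the miR-17-92 list may be too large. Without genes of several loci in both lists that log2 ratio was 5.15. Leaving genes out does not bring back the reads given to no gene, so this value cannot tell how large the gap is.

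The counts of the neuronal list were low beside those of the progenitor list. The neuronal list held 1.06% ± 0.077 of the counts, and the progenitor list exceeded it by 3.52 ± 0.22 on the log2 scale. Most of the neuronal share came from Mir127 (9170 ± 883 CPM), which also belongs to the Dlk1-Dio3 cluster. With the most abundant member of each list left out the log2 ratio was 5.95. Mir137, a miRNA of neurons, had 431 ± 100 CPM. Of the neuronal members 14 of 20 are genes of several loci, against 7 of 14 in the progenitor list, so more of the neuronal list was counted only as a lower limit. Leaving such members out of both lists gave a log2 ratio of 3.57. The reads given to no gene stay missing from that value, so it does not settle the gap either. Mir124a-2 of the neuronal list had 4.82 CPM, and Mir9-3 and Mir9-2 of the progenitor list had 339 and 5.58 CPM. These 3 genes were chosen after their values were seen and are uncertain for their several loci.

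Markers of hindbrain, trunk and red blood cells were rare. The Hox-cluster miRNAs, known from hindbrain, spinal cord and trunk, held 0.0277% ± 0.0046, with Mir10a at 115 ± 26 CPM and Mir10b at 92.6 ± 5.5 CPM, and lay at −8.79 ± 0.35 on the log2 scale against the progenitor list. Erythroid miRNAs held 0.0743% ± 0.0069, led by Mir451a (654 ± 74 CPM) and Mir144 (56.5 ± 4.8 CPM), at −7.36 ± 0.25 against the progenitor list. Without the most abundant member of each list this ratio was −9.98. Liver miRNAs held 0.0155% ± 0.00020, led by Mir194-2, which is uncertain for its several loci (73.6 ± 0.74 CPM), and Mir192 (70.8 ± 2.0 CPM). Without genes of several loci the liver share was 0.00833%. Muscle miRNAs held 0.00461% ± 0.00039, led by Mir208b of the Myh7 intron (28.0 ± 1.2 CPM) and Mir499 of the Myh7b intron (10.4 ± 0.064 CPM). Of the 8 counted muscle genes 3 are of several loci, so the muscle share is a lower limit. The X-linked testis cluster held 0.00035% ± 0.000065, with 13 and 11 counts over 18 genes, among them Mir741 (2.22 ± 0.77 CPM) and Mir743 (0.45 ± 0.24 CPM).

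Vessel, surface and mesenchyme miRNAs were more abundant than those of red blood cells or trunk. The endothelial and vessel wall list held 3.52% ± 0.19 of the counts, most of it Mir126a, with Mir143 at 3563 ± 395 CPM. Epithelial miRNAs held 0.971% ± 0.090, led by Mir429 (2994 ± 469 CPM) and Mir205 (2600 ± 5.6 CPM). The mesenchyme list held 0.819% ± 0.019, led by Mir214 (3850 ± 15 CPM) and the cartilage miRNA Mir140 (3237 ± 254 CPM), and lay at −3.89 ± 0.08 on the log2 scale against the progenitor list. Eye and sensory miRNAs held 0.836% ± 0.0022, led by Mir182 (4226 ± 83 CPM) and Mir183 (2416 ± 308 CPM). Leukocyte miRNAs held 0.879% ± 0.018, most of it Mir342 of the Evl intron (8107 ± 119 CPM), and Mir155 had 400 ± 25 CPM. The list share leaves out Mir142, whose hairpin was not among the counted genes.

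Among the broadly expressed families, miR-15 and miR-16 held 2.58% ± 0.015 of the counts with Mir322 and Mir15a (4876 ± 11 CPM) as its highest members. The miR-181 family held 1.69% ± 0.13, led by Mir181c (5888 ± 356 CPM) and Mir181d (5794 ± 468 CPM). The rodent Sfmbt2 intron cluster held 0.50% ± 0.055, led by Mir467c (2080 ± 181 CPM) and Mir467d (1350 ± 194 CPM). The miR-34 and miR-449 family held 0.211% ± 0.030, led by Mir34c (1203 ± 110 CPM) and Mir449a (749 ± 412 CPM). The Dlk1-Dio3 list lay at −0.97 ± 0.12 on the log2 scale against the miR-17-92 list.

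Against all 1973 genes, most of which had no count, the median level of 17 lists stood above the central 95% of random lists. The lists inside that range were the erythroid (percentile 95.9), liver (96.8), muscle (91.3) and X-linked testis (40.3) lists. Against only the 401 genes with a mean count of 10, the miR-17-92 (percentile 100), Dlk1-Dio3 (100), neural progenitor (99.4), miR-302 (99.1) and miR-181 (97.6) lists stayed above it. On that background the let-7 and Hox-cluster medians lay below the middle, at percentiles 35.7 and 28.2. Of the 10 counted let-7 genes 5 are of several loci and counted as a lower limit, so the let-7 percentile may be too low.

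The 2 pools gave similar profiles that nonetheless differed in several miRNA groups. Across 401 genes Pearson's r was 0.993 and Spearman's rho 0.991 on the log2 scale, where genes are not independent replicates. The biological coefficient of variation was 13.9%, the SD of the log2 ratio was 0.49, and the median size of the log2 ratio was 0.17. The libraries were not a library deposited again, since a chi-square statistic of 21863.5 on 482 degrees of freedom was 45.4 times what sampling noise gives. The exact binomial test called 174 of 401 genes different between the libraries, 79 higher and 95 lower in replicate 1, and 23 of them differed by more than 1.5-fold. At an unadjusted p of 0.05 the count was 194. Total-count scaling and DESeq2 size factors each gave 93 higher and 84 lower.

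**Figure D2:**
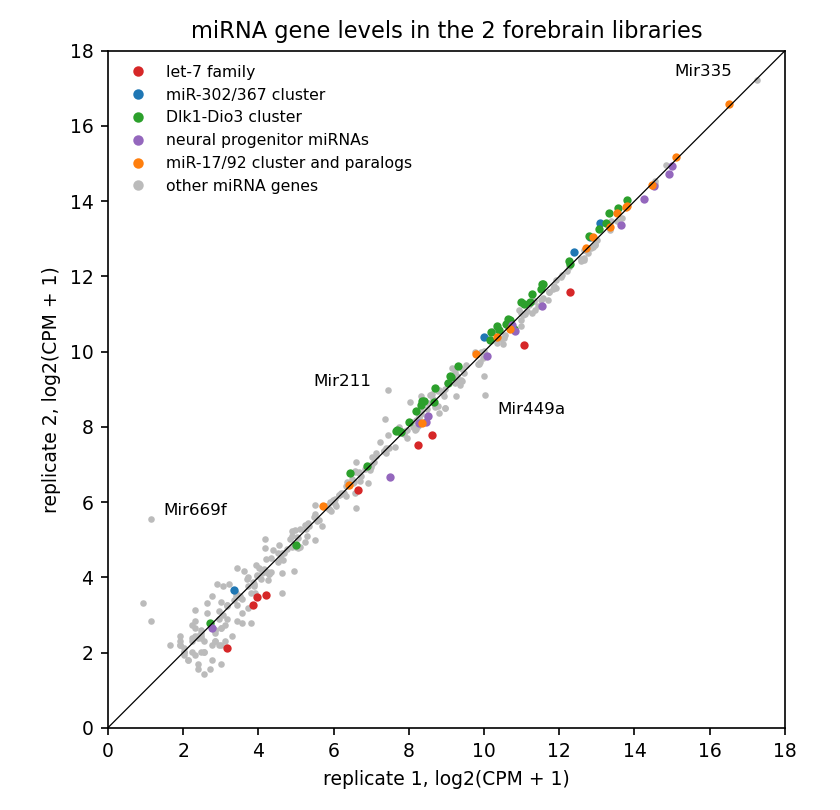
Level of each miRNA gene in replicate 1 (x axis) and replicate 2 (y axis), both as log2(CPM + 1), for the 401 genes with a mean count of 10 or more. Colours mark 5 lists, grey marks other genes and the line marks equal levels. Pearson's r across genes is 0.993, and let-7 members lie on the replicate 1 side of the line.

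The let-7 family was higher in replicate 1, in 9 of 9 genes. Its median log2 ratio was 0.68, higher than nearly all matched random lists (percentile 99.995), and its share was 0.795% (95% exact interval 0.785 to 0.805) in replicate 1 and 0.477% (0.470 to 0.484) in replicate 2. By the exact binomial test 6 members rose and none fell, with 7 rising when adjusted over the list alone. Mirlet7i rose by 0.84 (adjusted p = 1.3e-198, exact binomial test) and Mirlet7d by 0.80 (adjusted p = 2.4e-34, exact binomial test), both among the 5 highest ratios. The neural progenitor list was also higher in replicate 1, in 14 of 14 genes, by a smaller median of 0.17 (percentile 99.98). Of these genes 11 rose, or 12 adjusted over the list alone. Mir135a-2, which is uncertain for its several loci, rose by 0.80, and Mir99a and Mir92b of the same list rose by 0.18 and 0.16. The let-7 and progenitor lists are not fully separate, because Mir99a lies in a cluster with Mirlet7c-1 and Mir100 in a cluster with Mirlet7a-2. Mir100 and these let-7 genes were chosen after their values were seen, and the let-7 genes are uncertain for their several loci.

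The Dlk1-Dio3 and miR-302 clusters went the other way. Of 42 Dlk1-Dio3 genes 40 were lower in replicate 1, with a median log2 ratio of −0.25, below each of the 10000 matched random lists. The exact binomial test called 36 lower and 1 higher, with the same counts adjusted over the list alone. Mir487b fell by 0.28, Mir431 fell by 0.28 and Mir127 fell by 0.23. All 5 miR-302 genes were lower in replicate 1, with a median of −0.36 (percentile 0.08), and 4 of them fell, also when adjusted over the list alone. Mir302a fell by 0.36 and Mir302d fell by 0.28. The random lists drew genes 1 by 1, while clusters accounted for 58.1% of the variance of the ratio at a mean count of 100. The percentiles of the Dlk1-Dio3 and miR-302 clusters therefore overstate how far these lists stand apart. The miR-17-92 list, by contrast, had a median of −0.10 that did not stand apart (percentile 12.7), although 9 members fell and 1 rose. With total-count scaling or DESeq2 size factors 8 fell and 4 rose.

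**Figure D3:**
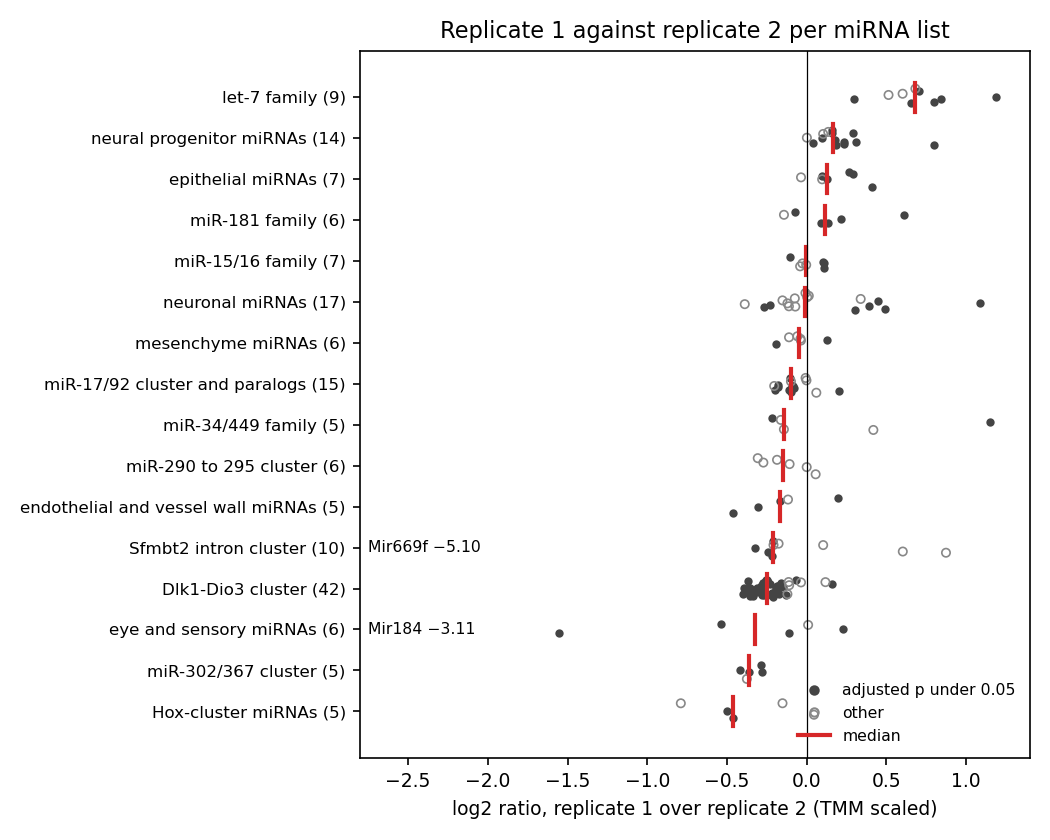
Log2 ratio of replicate 1 over replicate 2 for each gene of the lists with 5 or more tested genes (number in brackets). Filled points passed the exact binomial test at an adjusted p under 0.05, open points did not, and red bars mark medians, with 2 genes beyond the axis written out. Medians run from −0.46 for the Hox-cluster miRNAs to 0.68 for the let-7 family.

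Hox-cluster miRNAs had a median log2 ratio of −0.46 (percentile 0.31), with 2 of 5 genes falling, or 3 adjusted over the list alone. Mir10a, among the 5 lowest ratios, fell by 0.50 (adjusted p = 7.7e-06, exact binomial test). Eye and sensory miRNAs had a median of −0.32 (percentile 0.31), with 4 of 6 falling and 1 rising, or 3 falling and 2 rising with total-count scaling or DESeq2 size factors. Mir211, in an intron of the pigment cell gene Trpm1 at 64205806 to 64205911 of chromosome 7, fell by 1.55 (adjusted p = 4.4e-127, exact binomial test) and Mir204, in an intron of Trpm3, fell by 0.54. The Sfmbt2 cluster had a median of −0.21 (percentile 1.81) with 5 of 10 genes falling. Among genes with a mean count of 100 the eye and sensory list (percentile 29.5) and the Sfmbt2 list (4.55) no longer stood apart.

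Other lists did not stand apart in their ratio. Medians were 0.13 for epithelial, 0.11 for miR-181, 0.10 for leukocyte, 0.06 for muscle, −0.0027 for miR-15 and miR-16, −0.01 for neuronal, −0.01 for erythroid, −0.05 for mesenchyme, −0.05 for liver, −0.14 for miR-34 and miR-449, −0.15 for miR-290 and −0.17 for endothelial miRNAs. The X-linked testis list had no gene with enough counts. In these lists the gene with the highest ratio was Mir449a, a miRNA of multiciliated cells in an intron of Cdc20b, which rose by 1.15 (adjusted p = 1.8e-164, exact binomial test), also the highest among all genes with a mean count of 100. Outside the lists, Mir219a-2, uncertain for its several loci, rose by 0.72. Gm23935 fell by 0.86 and Mir6236 fell by 0.67.

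Neighbouring miRNA genes had similar levels. Over 414 genes in 104 clusters, the SD of the log2 level was 2.62 within clusters and 4.80 over all these genes, and cluster membership accounted for 70.2% of the variance (permutation p = 1e-05, the smallest that the shuffles can give). The miR-17-92 cluster on chromosome 14 held 15.8% of the counts in 6 genes. The Mir379 to Mir3072 stretch of the Dlk1-Dio3 region has 34 genes, and the 31 with a mean count of 10 or more held 7.90%. Levels still differed within the miR-17-92 cluster. Among its genes of a single locus they ran from 299 CPM for Mir19a, chosen after its values were seen, to 96278 CPM for Mir17. Among genes with a mean count of 10 the share fell to 16.7% (permutation p = 0.0068), with genes without counts left out.

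**Figure D4:**
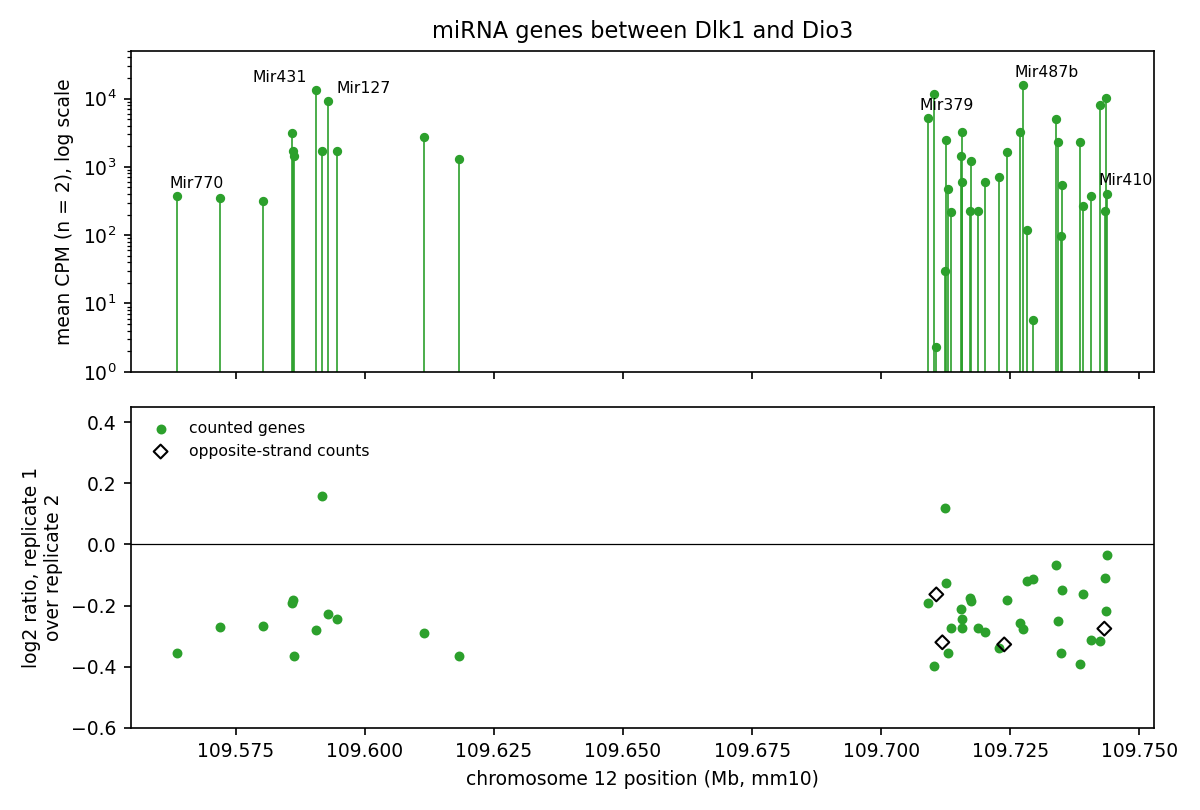
Genes of the Dlk1-Dio3 list along chromosome 12 (mm10, Mb), with mean CPM of 2 libraries on a log scale (top) and log2 ratio of replicate 1 over replicate 2 for genes with a mean count of 10 or more (bottom). Open diamonds are opposite-strand counts at 4 positions of the region. Of the 42 genes with a ratio 40 lie below 0, and the diamonds lie below 0 as well.

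Differences between the libraries were alike within clusters when weakly counted genes were left out. Over all 161 clustered genes with a mean count of 10, clusters accounted for −2.36% of the variance of the log2 ratio (permutation p = 0.46). This value rested on Mir669f of the Sfmbt2 cluster, chosen after its values were seen, with 4 counts in replicate 1 and 165 in replicate 2. Without Mir669f the clusters accounted for 47.3%, and among the 133 genes with a mean count of 100 for 58.1% (permutation p = 1e-05 in each, the smallest possible). In the miR-302 cluster the ratios lay between −0.42 and −0.28, and in the 31 tested genes of the Mir379 to Mir3072 stretch between −0.40 and 0.12.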

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

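The tests of opposite-strand counts below were chosen only after those counts were seen. Reads on the strand opposite to a listed gene enter no test of the report. They enter list shares only in the alternative with counts on either strand. On their own they appear in the report only beside the Dlk1-Dio3 share and on the map of that region. Yet they came to 111455 in replicate 1 and 134230 in replicate 2, far above the 3 counts that a count of 0 allows. At 9 genes there were 1000 or more such counts in each library, and these 9 held 99.5% of the total. Averaged over the libraries, the opposite-strand counts were 60849 at Gm24321, 12886 at Gm25252, 10458 at Gm25301, 9630 at Gm25750, 9026 at Gm24083, 8744 at Mir299b, 5195 at Gm25927, 3996 at Mir142b and 1492 at Mir497b. On their own strand these genes had between 0 and 10 counts per library.

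In the M21 annotation each of the 9 overlaps a miRNA hairpin on the other strand that is not among the counted genes. They are Mir409 (chromosome 12, 109743158 to 109743236), Mir376a, Mir378a, Mir380, Mir191, Mir299a, Mirlet7e (chromosome 17, 17830352 to 17830444), Mir142 and Mir497. Strand switching during library preparation would give each well-counted gene an opposite-strand share near the overall 3.31% and 3.62%. The median share was 0% over 163 genes with 1000 or more counts in each library, which argues against it at most of these genes. The highest share among them was 12.3%. Of the opposite-strand counts, 99.8% lay at genes that overlap such an uncounted hairpin. A candidate explanation is therefore that these reads come from miRNAs missing from the counted gene set; no biological explanation was tested.

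If so, the main list shares of the report leave these miRNAs out. The 4 positions in the Dlk1-Dio3 region had a median log2 ratio of −0.30, on the same side as the counted genes of that cluster. The position of Mirlet7e had 0.38, on the same side as the let-7 family. These values were looked at after the lists had been described, and Mir409 and Mirlet7e were among the members of the fixed lists that had no counted gene.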

How the results depend on the processing

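Alternatives named here were listed before the data were examined, except leaving out Mir669f, leaving out the Dlk1-Dio3 members and the other scalings of most named genes, which were chosen after seeing the data. Of the alternatives to the leading results, 96 gave the same call or a value within the spread, 16 moved, 3 gained a call and 2 reversed. For other lists and single genes the counts were 232 with the same call or a value within the spread, 32 moved, 8 losing a call, 2 gaining a call and 10 reversed. Both tallies include alternatives whose outcome was fixed in advance, so they overstate the stability of the results. They include a replicate left out of a mean of 2 values. Other scalings for the ratio percentiles of lists and for the SD of the log2 ratio are also among them.

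Leaving out a replicate moved no result by more than the spread, which for a mean of 2 values follows from how the SD is computed. Shares ranged from 0.477% to 0.795% for let-7, 22.1% to 23.1% for miR-17-92, 2.23% to 2.72% for miR-302, 11.5% to 12.8% for progenitor, 0.0245% to 0.0309% for Hox-cluster and 10.7% to 12.5% for Dlk1-Dio3 miRNAs. With total-count scaling or DESeq2 size factors no list's median ratio changed its call. This was fixed in advance, since another scaling shifts all log2 ratios by the same amount and leaves the percentiles as they were. The same shift turned the medians of the neuronal, erythroid and miR-15 and miR-16 lists, none standing apart, from just below to just above 0. Of 55 named genes 51 stayed on the same side of the threshold without a called gene changing sign, and 2 of these, Mir15a (0.0045 and 0.0042) and Mir499 (0.014 under each), not called under any scaling, turned from just below to just above 0. Mir30e, lower in replicate 1 by the main test at −0.03, had 0.0042 and 0.0039 and lost its call, Mir93 (0.024 under each) and Mir342 (0.030 under each) turned from near 0 to called higher, and Mir182 (0.040 under each) gained a call. The called genes numbered 163 to 177 over all alternatives.

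Among 401 genes with a mean count of 10 as background, the level percentiles lay on the other side of the middle for let-7 (35.7), Hox-cluster (28.2), miR-290 (16.9), neuronal (27.9), Sfmbt2 (24.2) and miR-34 and miR-449 (43.2) miRNAs, and also for the erythroid (33.0), liver (38.0) and muscle (9.88) lists, which had not stood apart, because genes without counts left the background. A minimum of 1 count detected 618 genes. The SD of the log2 ratio was 1.00 with no filter and 0.26 at a mean count of 100, since low counts vary more.

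Without Mir335 in the total, shares were 26.8% for miR-17-92, 2.93% for miR-302, 14.4% for progenitor, 0.0328% for Hox-cluster and 13.7% for Dlk1-Dio3 miRNAs, which follows from the smaller total. Counts on either strand gave 21.8% for miR-17-92 and 45.4% for the top 10 genes, and leaving out genes of several loci gave 48.4% for the top 10. Without the most abundant member of each list, log2 ratios were 5.86 (miR-17-92 over let-7), 5.95 (progenitor over neuronal), −9.98 (erythroid over progenitor), −4.37 (mesenchyme over progenitor) and −0.37 (Dlk1-Dio3 over miR-17-92), all in the same direction.

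Clusters accounted for 58.1% of the variance of the replicate difference at a mean count of 100, for 47.3% without Mir669f and for 54.5% at a mean count of 100 without Dlk1-Dio3 members. The main value rested on Mir669f.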

Other observations

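The straight-line GC correction and the tests on shared sequence within lists were set before their results were seen. The comparison with lists of the same GC and the tests on Mir204, Mir211 and the sensory miRNAs were chosen only afterwards. Genes outside the rule for named genes are described here after their values were seen. Outside the lists, 225 genes with a mean count of 10 or more were left, and genes outside the lists held 38.2% of the counts. After Mir335, Mir30e and Mir26b the most abundant were Mir30a (12564 ± 665 CPM), Mir130b (11567 ± 347 CPM), Mir423 (11053 ± 559 CPM), Mir149 (10097 ± 531 CPM) and Mir21a (8038 ± 106 CPM). Mir298 (6609 ± 411 CPM) and Mir296 (6526 ± 138 CPM), neighbours on chromosome 2, were nearly equal, with log2 ratios between the libraries of 0.10 and −0.07. Mir23b (5971 ± 619 CPM) and Mir27b (874 ± 80 CPM), neighbours on chromosome 13, had ratios of 0.18 and 0.16. Mir139 rose by 0.26 in replicate 1 and Mir423 fell by 0.13.

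The let-7 family was higher in replicate 1, while the miR-302 and Dlk1-Dio3 clusters were lower. A straight-line correction for hairpin GC decided nothing, because the trend was nearly flat (−0.01 on the log2 scale per 10% GC) and the medians stayed at 0.69, −0.35 and −0.23. Random lists of the same hairpin GC drawn from the other genes had a median of −0.053 for let-7 (central 95% −0.20 to 0.12). The medians were −0.058 for miR-302 (−0.31 to 0.20) and 0.0019 for Dlk1-Dio3 (−0.07 to 0.09). Other genes of the same hairpin GC thus did not share the shifts, but the miR-302 median of −0.36 lay only just outside its range. The lists were examined because they already stood apart from random lists, so matching on hairpin GC adds little. The GC of the sequenced fragments, shorter than 30 nt, was not tested, so an effect of GC content stays open. For Dlk1-Dio3, 13 of 42 members share no 10-base word with another hairpin of the list and still had a median of −0.27, with 12 of the 13 lower. This argues only against shared runs of 10 or more bases handled differently by the 2 preparations. Shorter shared motifs and the composition of the sequenced fragments were not tested, so other sequence-dependent effects of the preparations stay open. For let-7, 0 of 9 members lack a shared 10-base word, so shared sequence handled differently by the 2 library preparations cannot be told apart from a change of the family. A difference between the pools in developmental stage or dissection may also underlie the pattern, but no biological explanation was tested because both libraries belong to the same group.

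Mir211 (568 and 1793 counts), Mir204 (1034 and 1616 counts) and Mir184 (3 and 32 counts, chosen after its values were seen), known from the pigmented epithelium and lens of the eye, were lower in replicate 1. A bias on the near-identical mature sequences of Mir204 and Mir211 stays open: their log2 ratios differed by 1.01 (95% counting interval 0.84 to 1.19), but many genes differ between these libraries beyond counting error, so the gap decides nothing. Less of all eye and sensory tissue in replicate 1 stays open too: Mir182, Mir183 and Mir96 had a median log2 ratio of 0.0095, but the list was divided after its ratios were seen. Less eye tissue in the replicate 1 pool, all of it or only the pigmented epithelium and lens, may be a hypothesis, which these values cannot settle and for which the labels give no dissection difference.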
